A study of Mus musculus with 9 samples.

How the data were processed

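RNA-seq libraries were made from polyA RNA of dissected hippocampi and CLIP libraries from UV-crosslinked hippocampus tissue, per the labels' protocols. The 9 samples fall into 3 groups of 3, wild-type RNA-seq, Mbnl2 knockout RNA-seq and wild-type CLIP, as titles state. Reads were processed by the authors against the mouse build mm9, and the submitters' processing notes name TopHat 1.3.2, Bowtie and Novoalign; their settings and roles are not given in the sources used here, and the noted Bowtie version is left out because it could not be matched to a release.

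Counts of read pairs, junction fragments, raw reads, unique tags and mutations per library were deposited by the authors, and peak heights are counts of tags of the 3 libraries together, per the file headers. The change of exon inclusion is a fraction from the authors' comparison of genotypes, filtered to a junction coverage of at least 20, a false discovery rate of at most 0.05 and a change of at least 0.1, per the file headers. P-values, q-values and FDRs in the exon, array, ontology and mutation site tables are the authors' own, deposited without the name of the test, and 2 FDRs above 1 in the joint table show that it was not capped. Separation scores of the microarray and of RNA-seq reads were deposited by the authors with q-values, and the array platform and its normalization are not given in the sources used here. Fold enrichment in the ontology table is a ratio the authors deposited, listed up to an FDR of 0.1. Peaks were deposited at a P below 0.01 after Bonferroni correction and mutation sites at an FDR of at most 0.001 with at least 4 mutations, per the file headers. Tag files carry a score column that the authors deposited; it was not used, and tags were counted as lines.

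Values per library existed for read totals and CLIP tags, not for exons, so no model over animals could be fitted to splicing, and the planned test on the authors' lists was used. The authors list the CLIP libraries as biological replicates. Whether each CLIP library is from 1 animal is not stated, so spread between these libraries may be partly technical. Exon ends came from the joint table, since the end column of the RNA-seq list counts up by 1 per line. Inclusion changes with a division error, 2 in the joint table, were left out.

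Direction was read from depth, since no file names the genotype behind the sign. Reads of condition A exceeded those of condition B by a ratio of 1.44 over 151 events (135 events higher in A), close to the ratio of 1.42 for junction fragments in wild type over knockout. The median ratio over events was 1.39. A was therefore read as wild type. Events of the muscleblind genes went the other way, with 293 reads in A and 523 in B for the 36 nt event of Mbnl2, 110 and 199 for its 54 nt event and 56 and 75 for Mbnl1. The knocked-out gene thus has more reads in the condition read as knockout, and no file settles the reading apart from depth. The authors' change matched inclusion in A minus B in sign for 62 of 65 events shared by both tables (Pearson's r = 0.945 across events), so a positive change was read as less inclusion in the knockout. If that reading were wrong, every direction here would turn over; sizes would stay.

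Tags were counted on the strand of each feature. A tag was assigned to a peak or window by its centre, or by any overlap for tags per peak and heights; counted heights equalled the deposited ones for all 10407 peaks, and tag numbers for all 557 mutation sites. For each changed exon, log2((downstream + 1)/(upstream + 1)) was taken from tags within 1000 nt, with a pseudocount of 1. Differences of means were tested by two-sided permutation of exons with 100000 permutations. Shares carry 95% exact Clopper-Pearson intervals and were compared by two-sided Fisher's exact or exact binomial tests, with Benjamini-Hochberg adjustment within a family. Intervals cover counting error only, since amplified reads are not independent molecules. Pooled inclusion and skipping reads of 151 events were tested by Fisher's exact test, which called 102 events at an adjusted p of 0.05 (50 lower and 52 higher in the knockout). Inclusion on pooled reads is the share of inclusion reads among both kinds, not scaled for the number of junctions of each form. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

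The steps were tested on simulated data with fixed seeds. For the upstream and downstream comparison over 209 exons with real tag totals, 4.50% of 200 simulations without an effect and 100% with an odds ratio of 2 passed the threshold; the simulation holds binomial noise only. For the test on pooled reads, 79.1% of events changed by 0.2 were recovered and 1.29% of unchanged events were called among 151 events. This simulation also holds binomial noise only, without variation between animals, so 1.29% is not an error rate for the real events.

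Before the data were examined, the groups, tests, gene lists (6 functional and 6 cell type lists) and the rule for named genes were fixed. The rule takes the 12 largest inclusion changes per direction, up to 4 members per functional list with the largest change, the 8 largest array scores per direction, the 12 highest peaks with tags of all 3 libraries, 8 mutation sites, the 8 largest changes called by both platforms and the 10 exons with the most tags within 1000 nt, with Mbnl1 and Mbnl2 always given. Some genes that meet the rule are not used here. Genes outside the rule, such as Mag, Lingo2, Ablim1, the markers with most tags and the genes with most mutation sites, were named after their values were seen. The Fisher tests of exon counts by side and by 100 nt step were also added after the data were seen. Alternatives covered thresholds, windows, pseudocounts, tag collapsing and left-out CLIP libraries. Sequence motifs and unchanged exons were not analysed here.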

Results

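The series measured alternative splicing in the hippocampus of mice that lack Mbnl2, a muscleblind-like RNA-binding protein that regulates splicing, and mapped where the protein binds RNA. RNA sequencing covered 3 wild-type and 3 Mbnl2 knockout hippocampi from mice of 2 to 3 months, the knockout being a homozygous deletion named ΔE2. Crosslinking and immunoprecipitation (CLIP), which recovers short RNA tags bound by a protein, covered 3 wild-type hippocampus libraries. Their labels give an age of 11 to 12 weeks and female sex. The RNA-seq libraries held 18148581, 23902506 and 27844309 read pairs in wild type and 21196948, 21705237 and 8299323 in the knockout. Fragments spanning a splice junction, on which inclusion values rest, numbered 4443079, 5959853 and 6981448 in wild type and 5048806, 5166516 and 2035836 in the knockout. The third knockout library was the shallowest. The CLIP libraries held 159144, 209430 and 334857 unique tags. Exon values came as the authors' comparison of the genotypes, without values per animal, so the spread between animals behind them was not analysed here. The deleted part of Mbnl2 itself was not analysed here, and reads of other Mbnl2 exons were not lower in the condition read as knockout.

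The comparison of knockout with wild type asks which cassette exons depend on Mbnl2. In the hippocampus without Mbnl2, exons of 182 genes changed, and skipping and inclusion were about equally frequent. Of 209 changed exons, 106 were less included and 103 were more included in the knockout. The share of less included exons was 50.7% (95% exact interval 43.7 to 57.7%), and its difference from an even split was not past the threshold in a two-sided exact binomial test (p = 0.890). All 209 are cassette exons, the 1 event type analysed here, so event types were not compared. Each exon had passed the authors' limits of a junction coverage of 20, a false discovery rate (FDR) of 0.05 and a change of inclusion of 0.1. The median size of the change was 0.178 for less included and 0.185 for more included exons, as a fraction of transcripts. Directions rest on reading the deeper condition of the authors' tables as wild type, by depth alone.

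Among exons that lost inclusion, the largest change was in Cacna1d, which encodes an L-type calcium channel subunit. In the authors' deposited table, inclusion of its 60 nt exon on chromosome 14 (30942975 to 30943034, mm9) changed by 0.582 (FDR 3.62e-12). The 39 nt exon of Ndrg4 on chromosome 8 (98236225 to 98236263), a gene of the N-myc downstream-regulated family, changed by 0.411 in the authors' deposited table, with the lowest FDR named here, 3.04e-243. Pooled reads placed the Ndrg4 exon at 93.9% inclusion (95% exact interval 92.9 to 94.9%) in wild type and 67.1% (64.4 to 69.6%) in the knockout. St3gal3, a sialyltransferase, changed by 0.391 for its 48 nt exon and Limch1, an actomyosin regulator, by 0.371 for its 36 nt exon, per the authors' deposited table. Two-sided Fisher's exact tests on pooled reads gave an adjusted p of 2.31e-93 for Ndrg4 and 0.000129 for St3gal3. Pooled reads compare sets of libraries, not animals. Their inclusion is a share of raw reads, so its difference between genotypes is not the same measure as the authors' change and can be smaller.

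Other exons with large losses of inclusion lay in genes of varied function. The authors' deposited table lists changes of 0.416 for Nrxn3, a presynaptic adhesion protein, 0.389 for Adam22, a synaptic transmembrane protein, and 0.381 for the 84 nt exon of Camta1, a transcription activator. It also lists, as the authors' deposited table, 0.416 for Dab2, an endocytic adaptor, 0.394 for Ppap2a, a lipid phosphatase, 0.379 for Diap2, a formin, 0.359 for Ubn1, a chromatin protein, and 0.357 for Gas2, a cytoskeletal protein. FDRs of the named less included exons reached 0.0429, for Gas2, in the authors' deposited table.

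Exons that gained inclusion were led by 2510006D16Rik, with a change of 0.697 for its 127 nt exon in the authors' deposited table (FDR 3.36e-06). Dock10, an exchange factor for small GTPases, gained 0.574 for its 76 nt exon on chromosome 1 (80500494 to 80500569) per the authors' deposited table (FDR 2.19e-22). Gains in the authors' deposited table were 0.480 for the diacylglycerol kinase Dgkh, 0.464 for the phosphatase subunit Ppp2r5c and 0.358 for the myosin phosphatase subunit Ppp1r12a. Gains of 0.399 for Trerf1, 0.342 for Tcof1, 0.376 for Tac1, a neuropeptide precursor, 0.342 for Dzip3, a ubiquitin ligase, and 0.328 for Dlg2, a postsynaptic scaffold, are also in the authors' deposited table. The FDR was close to its limit for Tcof1 (0.0499) and Ppp2r5c (0.0495) in the authors' deposited table. Array scores pointed against the RNA-seq change for Ppp2r5c (0.28) and Gas2 (0.19 in size, q-value 0.014), and without passing a q-value of 0.05 for 2510006D16Rik (0.16) and Tcof1 (0.26), in the authors' deposited table.

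**Figure D1:**
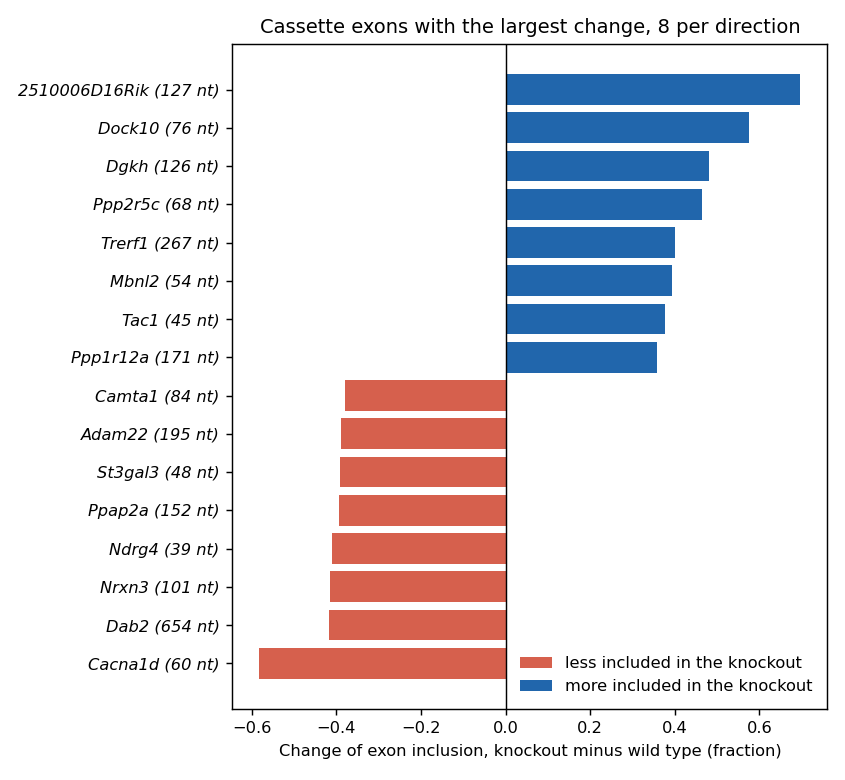
Bars give the change of exon inclusion in the knockout against wild type, as a fraction from the authors' deposited table, for the 8 exons with the largest change in each direction, 1 per gene, with exon lengths in nt. Cacna1d lost the most inclusion (0.582) and 2510006D16Rik gained the most (0.697); the table gives no error per exon.

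The muscleblind genes themselves changed in splicing. The 54 nt exon of Mbnl2 on chromosome 14 (120794934 to 120794987) gained 0.393 of inclusion in the authors' deposited table (FDR 8.81e-21). Pooled reads gave 64.5% inclusion (95% exact interval 54.9 to 73.4%) in wild type and 94.0% (89.7 to 96.8%) in the knockout. A 95 nt exon of Mbnl2 gained 0.222 in the authors' deposited table (FDR 1.92e-10). A 54 nt exon of the related gene Mbnl1 on chromosome 3 (60418605 to 60418658) also gained inclusion in the authors' deposited table (FDR 1.08e-06). Its pooled reads gave 57.1% in wild type and 73.3% in the knockout, a difference not past the threshold in Fisher's exact test (two-sided, adjusted p = 0.0802). For a 36 nt exon of Mbnl2, the array score had a size of 0.50 toward less inclusion, and the RNA-seq change had a size of 0.010 with an FDR of 0.894, per the authors' deposited table.

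Gene groups fixed before the data were examined were then counted among the 271 genes called by RNA-seq or the array. Of 65 synaptic scaffold, adhesion and vesicle proteins, 21 had a changed event, including Nrxn3, Dlg2 and Rims1, the last with a change of 0.282 toward more inclusion in the authors' deposited table. Of 62 cytoskeletal proteins and adaptors, 19 had one. Limch1 and Dst (0.281) were less included and Clip1 (0.249) more included in the authors' deposited table. Kinases, phosphatases and small GTPase regulators had 18 of 61, with Dgkh, Ppp2r5c, Ppp1r12a and Arhgap21 (0.348 toward less inclusion) changing most in the authors' deposited table. Of 50 ion channels and neurotransmitter receptors, 8 had a changed event. Cacna1d and a 29 nt exon of Kcnma1 (0.354), a potassium channel, were less included, and Grin1 (0.168), an NMDA receptor subunit, was more included in the authors' deposited table. RNA-binding and splicing proteins had 5 of 74, among them Mbnl2, Mbnl1, Tial1 (0.150 toward less inclusion) and Hnrnpr (0.140 toward more inclusion) in the authors' deposited table. Literature targets of muscleblind proteins or myotonic dystrophy had 21 of 42, led by Cacna1d, Dgkh, Ndrg4 and Mbnl2. Some members of that list are known from this study, so its count is not independent evidence. Cacna1d, Dgkh and Mbnl2 are also counted in the channel, kinase and RNA-binding lists. No share over all genes was computed, so none of these counts shows enrichment. None of the 6 lists passed the threshold against the other exons in the split of less and more included exons (two-sided Fisher's exact tests, lowest p = 0.208 for the RNA-binding list, 1 exon less and 4 more included, adjusted p = 0.833 over the 6 lists). Of the cell type markers, 1 gene, the oligodendrocyte gene Mag, had a changed exon; the neuron, astrocyte, microglia, endothelium and choroid plexus lists had 0.

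Gene ontology terms for these 271 genes came from the authors, with genes expressed in hippocampus as their background. In the authors' deposited table, synapse held 24 genes with a 3.28-fold enrichment (FDR 5.26e-05) and cell junction 28 genes at 3.17-fold (FDR 1.89e-05). Plasma membrane held 74 genes at 1.81-fold (FDR 1.05e-05), cytoskeleton 38 at 1.95-fold (FDR 0.00276) and synaptic transmission 14 at 3.46-fold (FDR 0.0356) in the authors' deposited table.

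Exon length bears on whether skipping keeps the reading frame. Changed exons were short, with a median of 61.5 nt among less included and 77 nt among more included exons, a difference not past the threshold in a two-sided permutation test of log2 length (p = 0.419). Lengths divisible by 3 made up 78.3% of less included exons (83 of 106, 95% exact interval 69.2 to 85.7%), among them the 60 nt Cacna1d and 39 nt Ndrg4 exons. Among more included exons the share was 73.8% (76 of 103, 64.2 to 82.0%), among them the 54 nt exons of Mbnl2 and Mbnl1. The difference of 4.52 percentage points was not past the threshold (two-sided Fisher's exact test, p = 0.517).

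The authors also compared knockout and wild type on a splicing microarray. Its column headings name brain, and whether this was hippocampus is not given in the sources used here. The question is whether both platforms moved the same exons in the same direction. Exons of Cacna1d, Dgkh, Ndrg4, Mbnl2, St3gal3, Limch1 and Ppp1r12a were called by both platforms and had the largest RNA-seq changes among 42 such exons. RNA-seq alone called 167 exons and the array alone 81. Not all exons could be compared, since 116 of the RNA-seq list had an array score. Array scores were largest, in size, for Kcnma1 (2.26), Limch1 (1.95) and Spna2 (1.73), a spectrin, among less included exons of the authors' deposited table. This Kcnma1 exon has 81 nt and an RNA-seq change of 0.274 in the authors' deposited table. It is not the 29 nt exon named above, which has no array score there. Among more included exons the authors' deposited table gives 2.38 for Tanc2, a synaptic scaffold, 1.72 for Dgkh and 1.51 for Ppp1r12a. Arpp21 (1.69) and Hivep2 (1.36) were called by the array with RNA-seq changes of 0.00157 and 0.0326 in size in the authors' deposited table, and the change of Hivep2 pointed the other way. Cyfip1 was also called by the array alone, with an RNA-seq change of 0.0845 (FDR 0.596) in the authors' deposited table. The other named array exons of the authors' deposited table were less included in St3gal3 (1.64), Cyfip1 (1.62), Ndrg4 (1.57) and Csnk1d (1.51), and more included in Mbnl1 (1.43), Add1 (1.37), Tom1l2 (1.32) and Spint2 (1.18).

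Scores had the same sign in 62 of 68 events past a q-value of 0.05 on both platforms (91.2%, 95% exact interval 81.8 to 96.7%; two-sided exact binomial test, p = 8.18e-13). Across these events, which are not independent replicates, Pearson's r was 0.808 and Spearman's rho 0.808 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give). The opposite events included exons of Gpr162, Nbr1, Ppp3ca, Saps2 and Odz4, named after their values were seen, with array scores of at most 0.444 in size in the authors' deposited table. The array's genotype columns are not named in the files, and its samples were not analysed here.

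**Figure D2:**
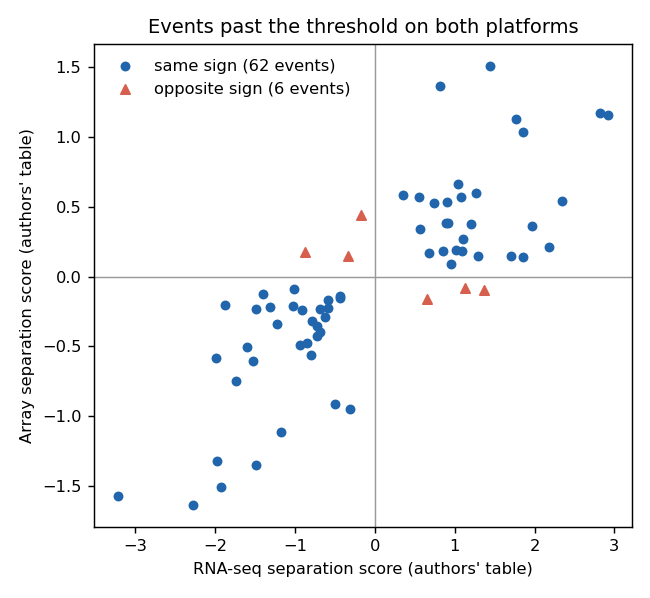
Each point is 1 of 68 events, with its RNA-seq separation score (x axis, no unit) and array separation score (y axis, no unit) from the authors' deposited table. The 62 circles have the same sign on both axes and the 6 triangles opposite signs, the latter all at array scores within 0.444 of 0.

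CLIP tags show which transcripts were recovered with Mbnl2 in wild-type hippocampus. The samples hold no knockout or input CLIP library, and tags were not scaled to transcript abundance. Peak heights therefore mix binding with abundance and background. The 12 highest peaks lay mostly in 3' untranslated regions (3'UTRs). App, the amyloid precursor protein gene, had 551 ± 174 tags per 1000000 unique tags (CPM) at its peak (SD, n = 3) on chromosome 16 at 84955009. Gnas, a G protein subunit, had 569 ± 262, and Snap25, a synaptic vesicle fusion protein, 412 ± 121 CPM (SD, n = 3). Mbp, a myelin protein, reached 361 ± 135, Cplx2, a complexin, 350 ± 146, and Clu, a chaperone, 320 ± 140 CPM (SD, n = 3). Chn1, Prnd, Rtn1 and Gpm6b followed at 289 ± 103, 270 ± 94.5, 251 ± 48.0 and 250 ± 50.8 CPM (SD, n = 3). Gene names of peaks, such as Prnd, are the authors' and were not checked against an annotation. A peak in an intron of Cdk8, in a repeat the authors list as ribosomal RNA, had 285 ± 174 CPM (SD, n = 3). Ttr, a choroid plexus transcript, varied most, with 157, 1031 and 281 CPM in libraries 1, 2 and 3. Mbnl1 and Mbnl2 transcripts carried 6 peaks each, the highest at 36.2 ± 7.67 and 23.2 ± 14.7 CPM (SD, n = 3), in their 3'UTRs.

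The authors called 10407 peaks on the pooled libraries, and 3'UTRs held 5742 (55.2%), introns 3538 (34.0%) and coding sequence 677 (6.51%). Peak heights in the authors' deposited table ranged from 2 to 359, with medians of 9 in 3'UTRs and 4 in introns. Tag centres of all 3 libraries fell inside 2697 peaks (25.9%, 95% exact interval 25.1 to 26.8%). That share depends in part on the narrow peaks, of a median 10 nt, and rose to 64.2% when any overlap of a tag counted. Among peaks of height 20 or more it was 37.7%. Across peaks, which are not independent, log2(CPM + 1) correlated at 0.34 between libraries 1 and 2, 0.42 between 1 and 3 and 0.50 between 2 and 3, with Spearman's rho of 0.393, 0.448 and 0.533.

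**Figure D3:**
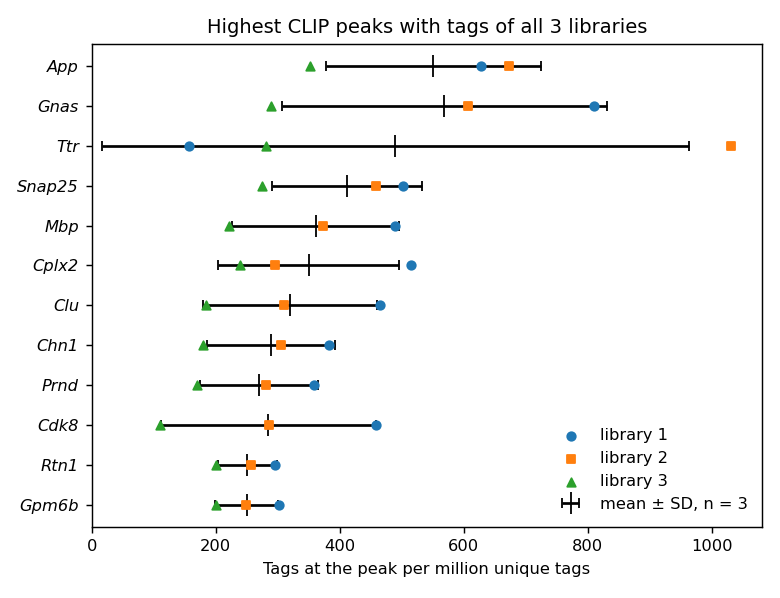
Points give tags at the peak per 1000000 unique tags (CPM) in each of the 3 wild-type CLIP libraries, and black bars the mean ± SD (n = 3), for the 12 highest peaks with tags of all libraries, 1 per gene. Ttr spreads from 157 to 1031 CPM.

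Markers of neurons and oligodendrocytes carried the most tags among the cell type lists, in counts not scaled to transcript abundance. Neuron markers held 2261 ± 411 and oligodendrocyte markers 2179 ± 509 CPM in their peaks (SD, n = 3), with Snap25, Camk2a and Mbp among the main contributors. Astrocyte markers held 776 ± 112, mainly Glul and Slc1a2, and endothelium markers 17.7 ± 17.4 CPM (SD, n = 3). Choroid plexus markers held 493 ± 475 CPM (SD, n = 3), nearly all from Ttr, and no peak was listed for the 5 microglia markers.

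Mutation sites induced by crosslinking are taken to mark bound nucleotides, which could not be tested here without a control CLIP library. The site with the most mutations lay in the Mbp 3'UTR on chromosome 18 at 82753588, with 28 mutations among 111 tags in the authors' deposited table, and an App 3'UTR site at 84955050 had 20 among 86. The other named sites carry no gene name in the authors' deposited table, and lie on chromosome 19 at 5798461 and 5798462 with 22 and 26 mutations, and on chromosome 17 between 39983843 and 39984723 with 18 to 23. The authors class those on chromosome 19 as 5'UTR and those on chromosome 17 as deep intergenic. In all, 152 sites carry no gene name. App held 21 sites, Snap25 18 and Mbp 10. Of 557 sites, 373 lay in 3'UTRs. Inside a peak lay 73 sites (13.1%, 95% exact interval 10.4 to 16.2%), against a median of 4.76% over 100 random placements at tag centres, all of them below that interval. Sites with at least 2 times the lowest mutation count numbered 83. Of these, 6.02% lay in a peak, close to the median of 4.82% for their placements, and no interval was computed for this small set. Of all 557 sites, 59.2% lay within 50 nt of a peak, against a median of 20.6% for placements. The placements were not matched to the sites in tag depth. A site needs at least 4 mutations, so depth alone could give an excess, and what the excess means stays open.

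Binding near the changed exons was compared between the directions of change, since no list of unchanged exons was analysed here. Peaks lay within 1000 nt of 9 of 106 less included exons (8.49%, 95% exact interval 3.96 to 15.5%) and of 15 of 103 more included exons (14.6%, 8.39 to 22.9%). The difference was not past the threshold (two-sided Fisher's exact test, p = 0.197). Of the 271 changed genes, 188 had a peak anywhere. Peaks named 4800 genes in all, and no share for unchanged genes was computed, so the count shows no enrichment.

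Tags were also counted on each side of the exons. Downstream of the 39 nt Ndrg4 exon, which lost inclusion, lay 80 tags, against 2 upstream, with 26, 21 and 33 downstream tags in libraries 1, 2 and 3. The less included exons of Spna2 and Mtap4, a microtubule-associated protein, had 36 and 33 tags downstream and 2 and 3 upstream. Among more included exons, that of Cadps, a vesicle priming protein, had 25 tags upstream and 0 downstream, and the 54 nt Mbnl2 exon had 19 upstream and 12 downstream. The other more included exons with the most tags had more of them downstream, in Klc1, a kinesin light chain (0 upstream, 28 downstream), Add1 (10 and 17, shared by 2 overlapping exons) and Kif1a (12 and 13). The less included exon of Nptn had 8 upstream and 13 downstream.

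Over all less included exons, 430 tags lay within 1000 nt downstream and 150 upstream; over more included exons, 228 lay downstream and 275 upstream. The mean log2 ratio of downstream to upstream tags was 0.53 ± 1.48 (SD over 106 exons) for less included and -0.15 ± 1.36 (SD over 103 exons) for more included exons. The difference of 0.68 was past the threshold (two-sided permutation test, 100000 permutations, p = 0.00058). Taken alone, libraries 1, 2 and 3 gave 0.26, 0.56 and 0.51, with permutation p of 0.0203, 3e-05 and 0.00307 (adjusted 0.0203, 9e-05 and 0.00461). More tags lay downstream than upstream of 51 less included exons and fewer of 26, against 33 and 40 more included exons (two-sided Fisher's exact test, p = 0.0134, a test added after the data were seen). In exons with at least 10 tags the difference was 1.68, over 36 exons.

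**Figure D4:**
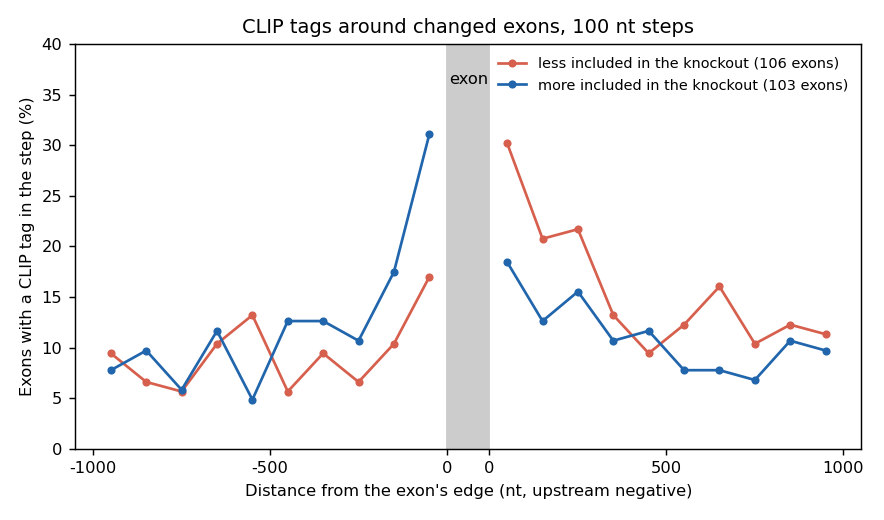
Lines give the percentage of exons with at least 1 CLIP tag centre in each 100 nt step (y axis) by distance from the exon's edge in nt (x axis), libraries pooled, for 106 less and 103 more included exons. In the step just downstream the values are 30.2% and 18.4%, and just upstream 17.0% and 31.1%; no step passed Fisher's exact test after adjustment over 20 steps (lowest adjusted p = 0.362).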

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

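All tests of the Y chromosome tags were chosen after those tags were seen. Tags on the Y chromosome appeared in all 3 CLIP libraries, whose labels say female, in data outside the comparisons. Libraries 1, 2 and 3 held 195, 234 and 257 such tags per 1000000 unique tags (31, 49 and 86 tags), where 3 counts, the limit that a count of 0 allows, would be 18.9, 14.3 and 8.96 per 1000000. The authors' deposited table lists 3 peaks there, 2 in Ddx3y, an RNA helicase gene, and 1 in Eif2s3y, a translation initiation factor gene. Ddx3y held 57.1% of the tags in its peaks and that of the X-linked copy Ddx3x (12 against 9, 95% exact interval 34.0 to 78.2%), but these peaks lie in different parts of the transcripts, so the share does not measure misplaced tags. All 3 libraries had tags in the Ddx3y peaks, which restates the pattern. The tags of the libraries together lay in 97 bins of 1 kb, 0 lay on the opposite strand of the Ddx3y peaks, and the authors' deposited table names 0 Xist peaks, which excludes none of the sources. Misplaced tags, tissue of male mice and wrong labels stay open as sources, and no biological explanation was tested.

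Substitutions per 100 mappable sequences, from columns outside the comparisons, numbered 26.9 in CLIP library 1, 10.9 in library 2 and 9.44 in library 3. Deletions numbered 6.93, 2.72 and 2.76 per 100, and deletions per substitution 0.257, 0.249 and 0.293. A number in the tag names, read as copies per tag, had medians of 26, 11 and 1 in libraries 1, 2 and 3. Whether it relates to the substitutions was not tested.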

How the results depend on the processing

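Alternatives chosen after seeing the data were overlapping exons reduced to 1, exons left out by their tags, windows inside introns, the wider sets of events and the peaks without each CLIP library. Any change of sign was counted as reversed, a stricter rule also chosen after the values were seen. No paired analysis was possible because exon values are not given per sample; for the same reason the planned replicate block and the planned fits without each RNA-seq replicate were not run. The tag difference around exons stayed past the threshold under all 15 alternatives (0.45 to 1.68, highest permutation p = 0.0477), and the agreement of platforms stayed past it under all 5 (76.7 to 97.5%). The count of changed exons fell from 209 to 103 at an FDR of 0.005 and 91 at a change of 0.2. Reads are listed for fewer exons, which left 48 with at least 20 and 45 with at least 100 reads. Fisher's test on pooled reads, on another set of 151 events, called 102. The less included share crossed an even split without passing the test, at 46.6% (FDR of 0.005), 47.9% and 48.9% (20 and 100 reads) and 49.0% (pooled reads). The reading frame difference ranged from 1.38 (1 exon per overlapping set) to 15.9 percentage points (change of 0.2, Fisher's exact p = 0.0954), against 4.52, and passed the threshold under none of 3 alternatives. The difference in nearby peaks turned from -6.07 to 1.98 percentage points at a change of 0.2, neither past the threshold. Peaks with all libraries made up 6.06% at 2 tags each, 64.2% with any overlap, 28.3% for peaks at least 2 times the lowest height, and 29.1 to 45.4% without a library, where fewer libraries are needed (highest without library 1). Correlations for libraries 1 and 2, 1 and 3, and 2 and 3 were 0.19, 0.27 and 0.33 at a pseudocount of 0.1, 0.59, 0.63 and 0.70 at 10, and 0.72, 0.68 and 0.73 for peaks with 30 tags. In 10 kb bins they were 0.40, 0.41 and 0.47. Mutation sites in peaks made up 59.2% within 50 nt and 6.02% for the 83 sites with at least 2 times the lowest mutation count. The latter compares with 4.82% for placements. Other causes were not tested. Depth limits low peaks, since the median height is 6 tags over 3 libraries.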

Other observations

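The tests on tags around exons inside introns and without the exons with most tags were chosen after the difference was seen; the comparison by direction and those without each library were planned, but how to read them as tests of an explanation was decided afterwards. The tests on Ttr were chosen after its uneven tags were seen, with a marker list written once it was known which of its genes have peaks. Camta1, Ablim1 and Tom1l2 had changed exons in both directions. In the authors' deposited table Ablim1, an actin-binding protein gene, lost 0.171 for a 141 nt exon and gained 0.184 for a 105 nt exon on chromosome 19. Tom1l2, an endosomal sorting gene, lost 0.235 for a 63 nt and gained 0.175 for a 60 nt exon in the authors' deposited table. On pooled reads the gained exon of Tom1l2 was not past the threshold (49.1% in wild type, 56.9% in the knockout, Fisher's exact test, adjusted p = 0.402), nor was the 31 nt exon of Camta1 (47.7% and 37.6%, adjusted p = 0.0688). Lingo2, a neuronal leucine-rich repeat gene, carried 80 CLIP peaks, the most of any gene, with a median height of 2 tags in the authors' deposited table. Of the 271 changed genes, 9 had a mutation site.

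The mean log2 ratio of downstream to upstream tags was higher by 0.68 for less included than for more included exons. With windows kept inside introns the difference was 0.92 (permutation p = 0.00533, 77 exons), against 0.66 for the same exons with full windows. The cut windows can differ in length between the sides and were not scaled for it. Windows reaching into constitutive exons are therefore not excluded as a cause. Without the 10 exons with the most tags the difference was 0.61 (permutation p = 0.001), and with each library left out the highest permutation p was 0.00384. Whether the side of binding sets the direction of change stays open, since the difference itself is the pattern, no unchanged exons give a baseline, and the mean of -0.15 for more included exons (SEM 0.13) lies close to 0.

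Ttr had 64.5% of its peak tags in CLIP library 2 (95% exact interval 59.1 to 69.6%), which holds 29.8% of all tags. The other choroid plexus markers with peaks, 8 of 15 genes led by Enpp2, which oligodendrocytes also express, had 43.0% (36.6 to 49.6%), above the library's share (exact binomial p = 2.24e-05) and below Ttr. These markers held 132, 482 and 337 CPM in libraries 1, 2 and 3, so the share of library 2 also reflects few tags in library 1. With tags collapsed to 1 per position Ttr kept 54.8% (46.9 to 62.5%), above the library's share, which argues against amplified copies as the whole source. The lower share of the other markers cannot decide whether choroid plexus tissue alone is the source. Enpp2 held most of their tags (16, 65 and 67 in libraries 1, 2 and 3), and its tags from oligodendrocytes could lower the share. With tags of Ttr and the other markers collapsed, the intervals overlap (42.9% for the other markers), a comparison added after the data were seen. Amplified copies and choroid plexus tissue together may account for the excess, a reading that was not tested, and no biological explanation was tested.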
